A study of Homo sapiens with 6 samples.

How the data were processed

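Per the labels, LX-2 cells, a human hepatic stellate cell line, were kept for 24 h with FEBJ (the fruit extract of Brucea javanica), with cynaroside or with DMSO, and total RNA was sequenced in 6 libraries, 2 per group. The labels gave no doses and did not say whether the 2 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries only, and that spread can be technical. Within pairs, the mean chi-square per row against a split by library size was 3.00 to 3.33 for 10 to 10000 counts of the pair. It was 3.93 to 3.96 above that, so the relative spread shrank as counts grew.

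Per the labels, the authors used CASAVA 1.7, HISAT2 (no version given), HTSeq 0.12.4 and DESeq2 1.38.0 with the hg19 build, and deposited raw counts for each library. The type of library kit, the strand setting of the counting step and the annotation release were not stated. Each of the 6 count tables held 62754 gene rows and 5 summary rows. The counts in gene rows summed to 2537896 and 3720981 for DMSO 1 and DMSO 2, to 2507734 and 3524136 for FEBJ 1 and FEBJ 2, and to 1599000 and 4709317 for cynaroside 1 and cynaroside 2. They made up 5.48 to 6.12% of all counts in a table, and the summary row for reads outside every feature held 87.4 to 88.3%. Summary rows were left out of library sizes and tests. In all, 26821 gene rows held at least 1 count.

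Gene symbols were joined by Ensembl identifier, which matched 62700 rows. Which genes overlap on opposite strands was taken from GENCODE release 29 on GRCh38, in which 58261 rows were present. The other 4493 rows were not in it and were given no overlap. The build named in the labels and this annotation were not reconciled, so no positions are reported. The annotation served to find which exons overlap and, in checks of explanations, for exon lengths and the order of genes. A row was read against an opposite gene when their exons overlapped by at least 50 bp. Rows said to have no opposite exon, 45633 in all, had no such overlap of any length.

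The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. After filterByExpr, 12012 rows were kept and scaled with TMM. A model of 3 group means without an intercept, with 3 residual degrees of freedom, was fitted to all 6 libraries, and the 3 comparisons were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within a comparison. A gene rose or fell where the adjusted p was at or under the 0.05 threshold. Levels are in CPM, counts over the TMM library size times 1e6, and are given as mean ± SD (n = 2). Log2 fold changes are given ± standard error.

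The 32 gene lists, the model, the threshold and the alternatives for the deposited counts were set before the data were examined. Lists with at least 5 tested members were compared with all other tested genes by camera from limma 3.58.1, with a preset inter-gene correlation of 0.01. Each such result is printed beside camera with an estimated correlation. The fry test from limma was the other alternative; it tests whether a list's genes move on balance one way and does not compare them with other genes. Members of each list were also counted after an adjustment over the list alone.

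The following genes were named by rule. In each comparison these were the 8 largest rises and the 8 largest falls among genes with a symbol, a mean of at least 5 CPM and both libraries of 1 group above both of the other. A panel of 10 fibrosis genes was set, of which 9 are reported here whatever their result. From each list that passed the threshold or had at least 3 members past it, up to 2 rising and 2 falling members with the smallest p were eligible. The member with the highest mean was named from each list of markers for other cell types. Where a group held 0 counts, the fold is a lower bound set by a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its 95% exact binomial interval. These intervals and floors cover counting error only.

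A further reading of the counts, the opposite-strand reading, was decided after the data were seen. In it, the counts of 1828 non-coding features were assigned to the single protein-coding gene whose exons lie opposite to them, provided that the feature held at least as many counts as the row of that gene. This gave 1699 genes, of which 1443 passed filterByExpr, and held 37.0 to 43.1% of the counts in gene rows. The same model and tests were applied. With protein-coding features included, 2852 features gave 2625 genes and 2290 were tested. Antisense and overlapping rows remain uncertain because the strand setting was not stated.

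The alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 2 libraries, a prior count of 2 for fold changes, a replicate block, leaving out each library, fitting only the 4 libraries compared, a threshold fold of 1.5 and DESeq2 1.42.0. Scaling by the opposite-strand reading and leaving out protein-coding rows with no opposite exon were added after the data were seen, as was a fit of each DMSO library as its own group, with 2 residual degrees of freedom, to correlate the treatments without a shared library. Leaving out 1 library of a pair leaves a lone library that is assumed to vary like the other groups.

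The code was tested on simulated data in which 200 genes were changed by known folds. In the opposite-strand reading, 2-fold changes were recovered for 81.2, 80.6 and 79.1% of the changed genes in the 3 comparisons, and 1.5-fold changes for 65.7, 65.2 and 51.5%. In the deposited rows, 2-fold changes were recovered for 35.5, 40.3 and 32.3%, so a 2-fold change in a deposited row was often missed. False calls made up 4.29, 1.85 and 3.92% of calls in the opposite-strand reading and 6.49, 4.65 and 1.41% in the deposited rows.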

Results

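The expression of genes was compared in LX-2 cells, a line of the stellate cells that lay down scar matrix in the liver. The cells had been kept for 24 h with FEBJ, a fruit extract of Brucea javanica and so a mixture, with cynaroside, a glucoside of the flavone luteolin, or with DMSO. Each group held 2 libraries, and the labels gave no doses. Gene rows held 1599000 to 4709317 counts per library, which was 5.48 to 6.12% of all counts in the tables. Log counts correlated at 0.955, 0.949 and 0.941 between the libraries of the DMSO, FEBJ and cynaroside groups, and at 0.726 to 0.829 between groups.

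Non-coding rows often held far more counts than the gene on the opposite strand. The row of GAPDH, a glycolytic enzyme, held 1508 and 2302 counts in the DMSO libraries, and the row opposite to it held 79831 and 115948. For VIM, an intermediate filament protein of mesenchymal cells, the own row held 1075 and 1455 counts and the opposite row 124589 and 181211. Antisense rows together held 43.5% of the counts in gene rows, and protein-coding rows held 44.6%. For 277 genes with at least 5000 opposite counts, the own row held a median of 3.99 and 3.74% of the opposite row in DMSO. The medians were 1.91 and 1.91% after FEBJ, and 1.03 and 1.1% after cynaroside. In 1157 pairs not chosen for a strong opposite row, with at least 1000 counts in the pair, they were higher. They were 9.59 and 9.41% in DMSO, 7.09 and 7.35% after FEBJ, and 4.09 and 3.92% after cynaroside. MT-ND6, the mitochondrial mRNA encoded on the other strand from the remaining 12, held 50.3 to 73.8% of the counts of the 13 mitochondrial mRNA rows. Results are therefore given in 2 readings, the rows as deposited and an opposite-strand reading decided after the data were seen. The opposite-strand reading assigns non-coding rows to the gene they oppose and covers 1443 tested genes.

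**Figure D1:**
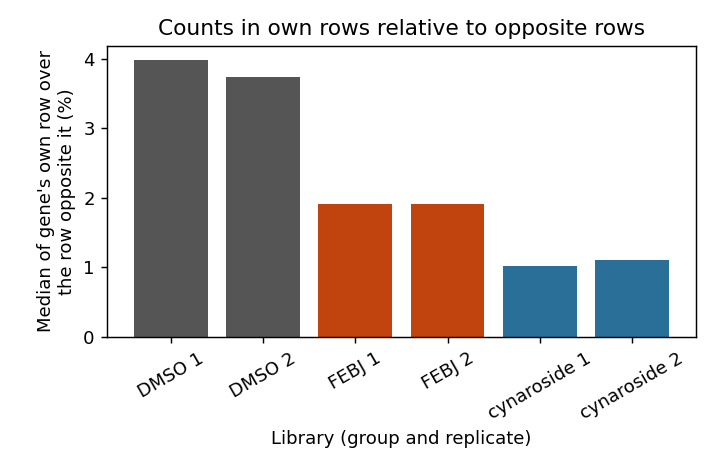
Median count of a gene's own row as a percentage of the row opposite to it, with 1 bar per library. The 277 genes were those with at least 5000 opposite counts. The percentage was highest in the DMSO libraries and lowest after cynaroside.

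The comparison of FEBJ with DMSO asked which transcripts the extract changed in stellate cells. After FEBJ, 4 of 5 tested matrix proteases, inhibitors and cross-linkers were lower in the opposite-strand reading, and all 5 tested immediate early genes were higher. LOXL2, a lysyl oxidase that cross-links collagen, fell from 2824 ± 114 to 136 ± 1.90 CPM (log2 fold change -4.37 ± 0.08). TIMP2, an inhibitor of matrix metalloproteinases, fell from 5879 ± 120 to 728 ± 68.9 CPM (-3.02 ± 0.05), and SPARC, a collagen-binding matrix protein, from 590 ± 9.98 to 34.6 ± 4.52 CPM (-4.07 ± 0.17). MCM2, a subunit of the replicative helicase, rose from 4102 ± 57.8 to 20988 ± 305 CPM, which was 5.12-fold. Of the 1443 genes, 518 rose and 498 fell, 300 and 290 of them more than 2-fold, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other 427 did not pass the threshold.

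Among stellate cell activation and fibrosis markers, 0 genes rose and 4 of 5 fell after FEBJ, and the counts were the same when adjusted over the list alone. VIM fell from 126119 ± 511 to 67076 ± 20.6 CPM (-0.91 ± 0.01), and THY1, a surface protein of fibroblasts, from 872 ± 5.05 to 538 ± 22.8 CPM (-0.70 ± 0.09). ACTA2, the smooth muscle actin that marks activated stellate cells and is read here from ACTA2-AS1, was not called, at 274 ± 8.21 CPM in DMSO and 304 ± 7.85 CPM after FEBJ (adjusted p = 0.318, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among matrix proteases, inhibitors and cross-linkers, 0 genes rose and 4 of 5 fell, also when adjusted over the list alone. These included LOXL1, a further lysyl oxidase (-1.61 ± 0.15), and P4HA2, a collagen prolyl hydroxylase (-1.25 ± 0.11). Of 4 YAP and TAZ target genes 3 fell, with the same count when adjusted over the list alone. AXL, a receptor tyrosine kinase, fell from 2229 ± 57.7 to 325 ± 14.4 CPM (-2.77 ± 0.07), and CRIM1, a membrane protein that binds growth factors, from 1252 ± 18.1 to 197 ± 14.1 CPM (-2.66 ± 0.10). The YAP and TAZ target AMOTL1 rose (0.43 ± 0.13). The stellate and matrix lists were both lower than other genes in camera, each with an adjusted p = 0.00263, or an adjusted p = 0.138 with an estimated correlation.

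**Figure D2:**
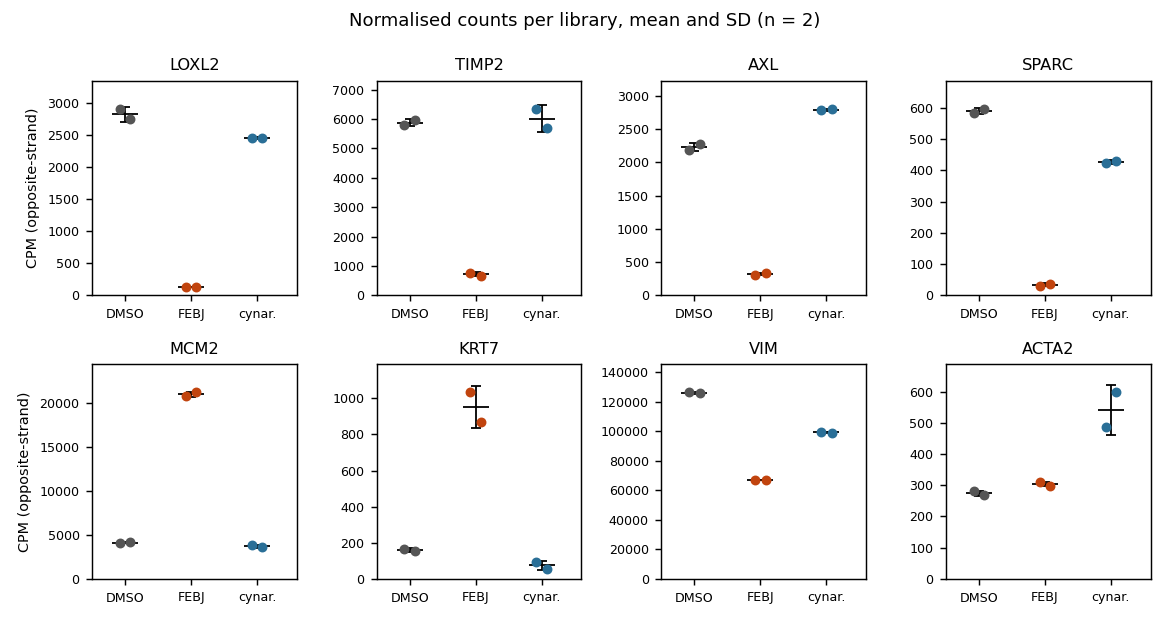
Levels in CPM on linear axes for 8 genes in the opposite-strand reading, with 1 point per library and bars for mean ± SD (n = 2) in DMSO, FEBJ and cynaroside. LOXL2, TIMP2, AXL and SPARC were lowest after FEBJ, and MCM2 and KRT7 were high only after FEBJ.

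All 3 tested genes of G1/S and DNA replication rose after FEBJ, out of 30 listed and too few for a list test, also when adjusted over the list alone, among them RRM1, a subunit of ribonucleotide reductase, from 638 ± 57.8 to 1540 ± 111 CPM (1.26 ± 0.08). All 5 immediate early genes rose, also when adjusted over the list alone. IER2 rose from 1660 ± 4.25 to 2870 ± 23.1 CPM (0.79 ± 0.06), and CSRNP1, a nuclear protein, from 48.7 ± 12.9 to 194 ± 10.2 CPM (2.02 ± 0.24). The immediate early list was higher than other genes in camera (adjusted p = 0.0389), with an adjusted p = 0.173 with an estimated correlation. The deposited rows of the same lists moved otherwise, with 6 of 26 G1/S rows risen and 6 fallen, also when adjusted over the list alone, and 0 of 15 immediate early rows risen and 5 fallen, or 0 and 4 when adjusted over the list alone. KRT7, a keratin of bile duct epithelium, rose from 160 ± 8.79 to 952 ± 115 CPM (2.57 ± 0.13). Of the apoptosis regulators, BMF (2.15 ± 0.51) and BCL2L11 (0.71 ± 0.15), which favour cell death, rose and the survival factor BCL2L1 fell from 2107 ± 122 to 788 ± 17.2 CPM (-1.42 ± 0.07). The list of apoptosis regulators was not past the threshold in camera (adjusted p = 0.961).

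All 4 tested genes of the unfolded protein response fell after FEBJ, too few for a list test, also when adjusted over the list alone. EDEM1, which directs misfolded glycoproteins to degradation, fell from 310 ± 21.3 to 52.5 ± 2.01 CPM (-2.56 ± 0.18), and CALR, a chaperone of the endoplasmic reticulum, from 2514 ± 195 to 1436 ± 68.1 CPM (-0.80 ± 0.06). Of 4 cholesterol synthesis genes 3 fell, also when adjusted over the list alone. HMGCS1, an enzyme at the start of the pathway, fell from 1161 ± 1.93 to 513 ± 62.1 CPM (-1.18 ± 0.09). Of 4 genes of fatty acid synthesis and lipid storage 1 rose and 2 fell, also when adjusted over the list alone. DGAT2, which makes triglycerides, rose from 131 ± 17.8 to 574 ± 21.4 CPM (2.15 ± 0.15). Of 4 genes of the ATF4 response 1 rose and 2 fell, also when adjusted over the list alone. The amino acid transporters SLC7A5 (-1.08 ± 0.20) and SLC1A5 (-1.13 ± 0.07) fell. Of 2 tested NRF2 target genes, the quinone reductase NQO1 fell (-2.04 ± 0.15) and the transcription factor MAFG, chosen after its values were seen, rose (0.91 ± 0.16).

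The largest falls by rule after FEBJ also included LRP1, an endocytic receptor (122 ± 5.55 to 7.51 ± 4.67 CPM, -4.10 ± 0.34), ITGA6, a laminin-binding integrin (-3.86 ± 0.30), and the chromatin protein HMGA2 (-3.95 ± 0.83). CHUK, a kinase of the NF-kB pathway, was 28.2-fold lower as a ratio of counts (interval 7.46 to 239). Among the largest rises, ARHGEF33 had 0 counts in DMSO and was at least 25.8-fold higher, and POU2AF3 and CASS4 were at least 20.2-fold and 19.8-fold higher. VIPR1, a receptor for vasoactive intestinal peptide, rose from 2.72 ± 1.89 to 126 ± 8.40 CPM (5.60 ± 0.49). Adjusted p for VIPR1 was 6.26e-29 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the calls of these genes held when any 1 library was left out. Neither measures variation between cultures, as the 2 libraries of a group may be repeats of the same culture.

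In the rows as deposited, 3125 of 12012 rose and 2982 fell after FEBJ by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2325 and 2520 of them more than 2-fold. Scaled by the opposite-strand reading instead, 2639 rose and 3607 fell, and the median log2 fold change moved from -0.06 to -0.28. Protein-coding rows with no exon opposite to them were lower as a group, with a median of -1.03, and 467 of 3892 rose and 1348 fell. Most genes of the fibrosis panel belong to this group. For 625 genes outside it that have both rows, own-row and opposite-strand log2 fold changes correlated at 0.459. COL1A1, the main chain of type I collagen, fell from 293 ± 23.7 to 2.61 ± 0.317 CPM (-6.77 ± 0.27), and FN1, fibronectin, from 228 ± 8.52 to 26.3 ± 3.89 CPM (-3.13 ± 0.17). COL3A1, a chain of type III collagen, was at least 18.0-fold lower, and PDGFRB, the PDGF receptor of stellate cells, at least 13.3-fold lower, each with 0 counts after FEBJ. The TGFB1 row, which lies opposite HNRNPUL1, fell by 0.67 ± 0.07 log2.

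The weakest panel rows lost their calls when single libraries were left out, mostly at similar folds. TIMP1, an inhibitor of metalloproteinases, fell after FEBJ (-1.92 ± 0.78, adjusted p = 0.0416), but the log2 fold change was -0.995 without DMSO 1 (adjusted p = 0.597), -2.14 without FEBJ 1 (0.0873), -1.71 without FEBJ 2 (0.157) and -1.79 with a replicate block (0.0844). The ACTA2 row, which lies opposite other annotated exons, fell as a ratio of 10.7 (interval 3.40 to 54.4, adjusted p = 0.0359), with a log2 fold change of -3.21 that was -3.65 without DMSO 1 (0.0794), -3.97 without FEBJ 1 (0.0788), -2.63 without FEBJ 2 (0.210) and -3.07 with a replicate block (0.114). CCN2, a matricellular growth factor, was not called, at 8.35 ± 2.18 and 6.05 ± 0.674 CPM (adjusted p = 0.562). COL1A2 had 0 counts in all 6 libraries. All of these values came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

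**Figure D3:**
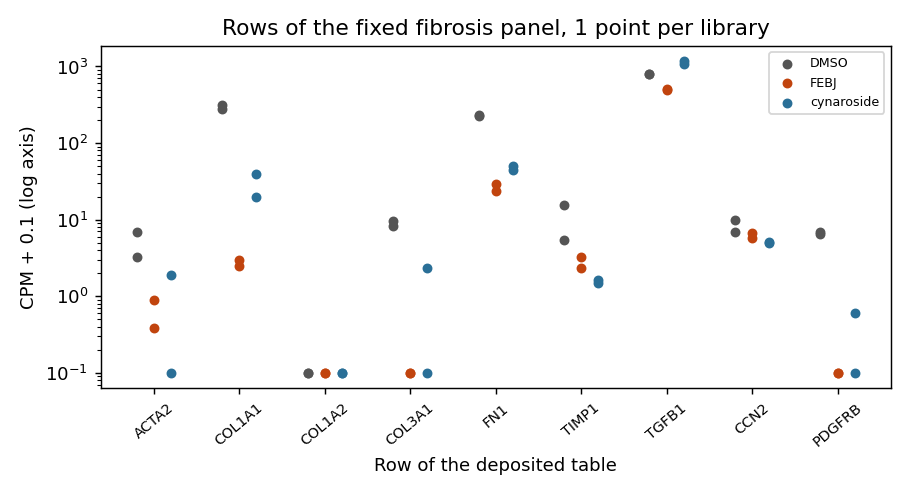
CPM plus 0.1 on a log axis for 9 fibrosis panel rows as deposited, with 1 point per library in DMSO, FEBJ and cynaroside. COL1A1 and FN1 were lowest after FEBJ and intermediate after cynaroside, and COL1A2 had no counts.

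Camera placed 11 of 29 lists past the threshold in the deposited rows, all lower after FEBJ, and 0 lists with an estimated correlation. All 13 mitochondrial mRNA rows fell (adjusted p = 4.75e-22, or an adjusted p = 0.170 with an estimated correlation), with MT-CO1, a subunit of cytochrome c oxidase, at -3.23 ± 0.10. MT-ND6, encoded on the other strand, held 50.3 to 73.8% of their counts, so these rows may not give the levels of the genes they name. Of 19 stellate cell markers 1 rose and 16 fell, and of 14 collagens 1 rose and 11 fell, with the same counts when adjusted over the list alone. Of 21 cytosolic heat shock proteins 2 rose and 11 fell, or 3 and 11 when adjusted over the list alone, among them the chaperone HSPA8 (-4.75 ± 0.19). Of 42 ribosomal proteins 1 rose and 33 fell, and of 22 glycolysis and hypoxia genes 2 rose and 12 fell, also when adjusted over the list alone. The glycolysis list included the GAPDH row (-2.27 ± 0.11), but GAPDH in the opposite-strand reading rose (0.10 ± 0.01). Of 28 G2/M genes 1 rose and 19 fell, or 1 and 20 when adjusted over the list alone, with TOP2A, a topoisomerase of dividing cells, at -3.47 ± 0.32. Camera compared these lists with all rows, while protein-coding rows with no opposite exon as a class had a median of -1.03. The medians of these 11 lists ran from -2.91 for collagens to -1.09 for NRF2 target genes. As the lists were picked for being low and none was tested against that class, their medians do not show a fall beyond it.

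Markers of hepatocytes and macrophages were scarce, with at most 37 and 32 counts in any library, while those of endothelial cells reached 671 and those of bile duct and other epithelium 6170. The epithelial marker with the highest mean, the KRT8 row, lies opposite KRT18, so its counts may be reads of that gene. SERPINA1, a hepatocyte protein, rose after FEBJ from 0.475 ± 0.328 to 10.6 ± 0.176 CPM, a ratio of 24.5 (interval 8.02 to 122). Of 3 macrophage markers 2 rose, or 3 when adjusted over the list alone. CSF1R, a macrophage receptor, was not called over all rows, at 1.49 and 5.82 CPM (adjusted p = 0.0759 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but was with only the 4 libraries compared (0.0438). The KRT8 row, opposite KRT18, was not called either, at 1498 ± 2.50 and 1421 ± 10.5 CPM (adjusted p = 0.334). It was called lower under 6 alternatives, at 0.00351 with RLE scaling, 0.00120 with upper-quartile scaling, 0.00146 with DESeq2, 0.0409 with only the 4 libraries compared, 1.17e-05 with the scaling of the opposite-strand reading and 2.47e-08 without protein-coding rows with no opposite exon. The STAB1 row, opposite NT5DC2, rose by 0.36 log2 (adjusted p = 0.0167), a call that ended at 0.202 without DMSO 1, 0.136 without DMSO 2, 0.170 without FEBJ 1 and 0.0922 without FEBJ 2. The STAB1 fold itself was 0.14 with the scaling of the opposite-strand reading (0.291) and 0.00 without protein-coding rows with no opposite exon (0.998), and the call also ended with RLE (0.0616) and upper-quartile scaling (0.0923). With 2 libraries per group of unstated origin, these tests do not measure variation between cultures.

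The comparison of cynaroside with DMSO asked which transcripts the flavone glucoside changed. In the opposite-strand reading cynaroside moved fewer genes than FEBJ, and LOXL2 and TIMP2 stayed closer to their DMSO levels. ACTA2 rose from 274 ± 8.21 to 542 ± 79.2 CPM (1.00 ± 0.13), and VIM fell from 126119 ± 511 to 99415 ± 214 CPM (-0.34 ± 0.01). TPM1, a tropomyosin of the contractile cytoskeleton, fell from 6449 ± 141 to 3081 ± 158 CPM (-1.07 ± 0.04), and LOXL2 fell slightly, from 2824 ± 114 to 2453 ± 8.90 CPM (-0.20 ± 0.06). TIMP2 was not called, at 5879 ± 120 and 6013 ± 466 CPM (adjusted p = 0.608). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 288 of 1443 genes rose and 310 fell, 69 and 86 of them more than 2-fold, and 845 did not pass the threshold.

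IER3, an early response gene, fell after cynaroside from 464 ± 34.2 to 75.3 ± 3.23 CPM (-2.61 ± 0.15), and IER2 from 1660 ± 4.25 to 1153 ± 10.5 CPM (-0.53 ± 0.06), while the nuclear receptor NR4A1 rose from 124 ± 6.80 to 415 ± 24.4 CPM (1.73 ± 0.15). Of 5 immediate early genes 1 rose and 3 fell, also when adjusted over the list alone. All 3 called genes of fatty acid synthesis and lipid storage fell, or all 4 tested when adjusted over the list alone, and HMGCS1 of the cholesterol pathway fell from 1161 ± 1.93 to 544 ± 43.5 CPM (-1.11 ± 0.09). Of 4 genes of the ATF4 response 3 fell, also when adjusted over the list alone, among them the amino acid transporters SLC1A5 (-0.80 ± 0.07) and SLC7A5 (-1.10 ± 0.20). In the unfolded protein response 2 genes rose, or 2 rose and 1 fell when adjusted over the list alone, with EDEM1 at 0.61 ± 0.14 and HYOU1, a chaperone of the endoplasmic reticulum, at 0.45 ± 0.07. The deposited rows of this list differed, as 1 of 22 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.000634, or an adjusted p = 0.111 with an estimated correlation). BCL2L11 rose from 168 ± 14.1 to 410 ± 4.22 CPM (1.28 ± 0.15), and KRT7 fell from 160 ± 8.79 to 74.1 ± 25.9 CPM (-1.24 ± 0.17).

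Of 5 stellate cell markers 1 rose and 3 fell after cynaroside, or 2 and 3 when adjusted over the list alone. Of 5 matrix proteases, inhibitors and cross-linkers 2 fell, and of 4 YAP and TAZ targets 1 rose and 2 fell, or 2 and 2 when adjusted over the list alone. AXL rose from 2229 ± 57.7 to 2793 ± 13.5 CPM (0.33 ± 0.06) and CRIM1 fell (-0.31 ± 0.08). Camera from limma placed 0 of 5 lists past the threshold, with 0 at an unadjusted p under 0.05. The smallest adjusted p = 0.356, and the smallest was an adjusted p = 0.635 with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way and not whether they differ from other genes, placed 2 lists past the threshold, the stellate markers (adjusted p = 0.000862) and the immediate early genes (adjusted p = 0.0181), both lower.

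By rule, the largest rises after cynaroside included PDE10A, a phosphodiesterase, from 7.37 ± 0.373 to 111 ± 20.4 CPM (3.91 ± 0.40), DNAI4, a dynein subunit (3.45 ± 0.49), and ARHGEF33, at least 13.8-fold higher. The largest falls included LY6K, a surface protein, from 65.4 ± 5.14 to 8.81 ± 4.03 CPM (-2.71 ± 0.40), and PTPRB, a receptor phosphatase (-2.30 ± 0.36). ROBO4, a guidance receptor, fell (-3.48 ± 0.87, adjusted p = 0.000281 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 0.0607 without DMSO 1. FAM110A fell (-3.37 ± 0.95), with an adjusted p of 0.0549 without cynaroside 1.

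In the deposited rows 2917 of 12012 rose and 2537 fell after cynaroside by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1512 and 2313 of them more than 2-fold. This split depended on the scaling: with that of the opposite-strand reading 1428 rose and 3805 fell, with upper-quartile scaling 2260 and 3015, and with only the 4 libraries compared 2311 and 3052. The median log2 fold change moved from 0.02 to -0.44 with the scaling of the opposite-strand reading. Without DMSO 1 the number of falls was 1618 and without DMSO 2 it was 1543. Protein-coding rows with no opposite exon had a median of -1.41, and 330 of them rose and 1523 fell. For 625 genes with both rows, own-row and opposite-strand log2 fold changes correlated at 0.0778, with medians of -0.893 and -0.0172. Falls in own rows were thus a poor guide to the opposite-strand reading of the same gene. COL1A1 fell from 293 ± 23.7 to 29.7 ± 14.2 CPM (-3.46 ± 0.20) and FN1 from 228 ± 8.52 to 46.6 ± 3.92 CPM (-2.31 ± 0.16). The TGFB1 row, which lies opposite HNRNPUL1, rose from 792 ± 6.76 to 1112 ± 69.9 CPM (0.49 ± 0.07), but was at 0.03 with the scaling of the opposite-strand reading.

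Weak panel rows after cynaroside again rested on few counts. COL3A1 fell by 2.57 log2 (adjusted p = 0.0323). Its call was lost without DMSO 1, DMSO 2 or cynaroside 1, at log2 fold changes of -2.74, -2.54 and -1.92. PDGFRB fell as a ratio of 18.0 (interval 4.70 to 153, adjusted p = 0.0127). Its call was lost without DMSO 1 and without DMSO 2, at log2 fold changes of -4.20 and -4.09. TIMP1 fell (-2.78 ± 0.86, adjusted p = 0.0103), but without DMSO 1 the log2 fold change was -1.86 and the call was lost. The ACTA2 row (adjusted p = 0.132) and CCN2 (adjusted p = 0.354) were not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

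Camera placed 15 of 29 lists past the threshold in the deposited rows, all lower after cynaroside, and 0 with an estimated correlation. Camera compared them with all rows, while protein-coding rows with no opposite exon as a class had a median of -1.41. The medians of these 15 lists ran from -2.34 for the nuclear-encoded respiratory chain to -0.80 for TGF-beta genes. These lists too were picked for being low and were not tested against that class, so their medians do not show a fall beyond it. Of 42 ribosomal proteins 2 rose and 31 fell (adjusted p = 1.50e-09, or an adjusted p = 0.0645 with an estimated correlation). Of 19 stellate cell markers 2 rose and 14 fell, and of 14 collagens 0 rose and 9 fell, with the same counts when adjusted over the list alone. Of 22 glycolysis and hypoxia genes 3 rose and 14 fell, or 5 and 14 when adjusted over the list alone, with the kinase PKM at -2.83 ± 0.15. The mitochondrial mRNA rows were split, with 5 risen and 8 fallen and the MT-ND6 row up by 1.47 ± 0.05 (list adjusted p = 0.391). Because the strand of their reads is uncertain, these rows may not give the levels of the genes they name. Of 6 endothelial markers 4 rose and 0 fell, also when adjusted over the list alone. Camera gave that list an adjusted p = 0.211, or an adjusted p = 0.331 with an estimated correlation, while fry, which tests whether a list's genes move on balance one way and not against other genes, placed it up (adjusted p = 0.00172). Among marker rows of other cell types, the KRT8 row fell from 1498 ± 2.50 to 575 ± 3.24 CPM (-1.38 ± 0.07). SERPINA1 and CSF1R were not called (adjusted p = 0.188 and 0.334 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The STAB1 row rose by 0.42 log2 (adjusted p = 0.00791 by the same test), a call that ended with RLE (0.0618) and upper-quartile scaling (0.127). It also ended without DMSO 1 and without DMSO 2, at log2 fold changes of 0.39 and 0.42. The STAB1 fold was -0.0459 with the scaling of the opposite-strand reading and 0.07 without protein-coding rows with no opposite exon.

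The comparison of FEBJ with cynaroside asked where the mixture and the single glucoside differed. Of 5 tested matrix proteases, inhibitors and cross-linkers 4 were lower after FEBJ than after cynaroside in the opposite-strand reading, and the 3 tested replication genes were higher. LOXL2 was lower, at 136 ± 1.90 against 2453 ± 8.90 CPM (-4.17 ± 0.08), and TIMP2, at 728 ± 68.9 against 6013 ± 466 CPM (-3.05 ± 0.05). AXL was at 325 ± 14.4 against 2793 ± 13.5 CPM (-3.10 ± 0.07), and SPARC at 34.6 ± 4.52 against 427 ± 5.54 CPM (-3.60 ± 0.18). KRT7 was higher after FEBJ, at 952 ± 115 against 74.1 ± 25.9 CPM (3.82 ± 0.15), and MCM2 by 2.50 ± 0.03. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 513 of 1443 genes were higher and 492 lower, 310 and 279 of them more than 2-fold, and 438 did not pass the threshold.

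All 5 stellate cell markers were lower after FEBJ than after cynaroside, and of 5 matrix proteases, inhibitors and cross-linkers 1 was higher and 4 were lower, with the same counts when adjusted over the list alone. ACTA2 was at 304 ± 7.85 against 542 ± 79.2 CPM (-0.85 ± 0.13). Both lists were lower in camera (adjusted p = 0.000564, or an adjusted p = 0.0984 with an estimated correlation). The higher matrix gene, LOXL4 (2.31, adjusted p = 0.0346 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), lost its call without FEBJ 2 (0.510), without either cynaroside library (0.134 and 0.173), without either DMSO library (0.0648 and 0.0605) and with a replicate block (0.0534). All 4 genes of the unfolded protein response were lower, with EDEM1 at -3.17 ± 0.17 and HYOU1 at -1.22 ± 0.07, and 3 of 4 cholesterol synthesis genes, in both cases also when adjusted over the list alone. Of 5 immediate early genes 4 were higher and 1 lower, also when adjusted over the list alone, with IER3 at 2.91 ± 0.15 (list adjusted p = 0.0210, or an adjusted p = 0.325 with an estimated correlation).

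All 3 tested interferon-stimulated genes, of 32 listed and too few for a list test, were higher after FEBJ than after cynaroside, also when adjusted over the list alone. In the deposited rows 2 of 10 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.861, or an adjusted p = 0.892 with an estimated correlation). Those of the opposite-strand reading included MX1, an antiviral GTPase, at 140 ± 2.79 against 23.7 ± 10.3 CPM (2.42 ± 0.30), and XAF1, a partner of apoptosis inhibitors, at 177 ± 20.6 against 85.8 ± 1.25 CPM (1.04 ± 0.20). The transcription factor CEBPB was at 770 ± 39.6 against 336 ± 28.7 CPM (1.17 ± 0.10), and DGAT2 at 574 ± 21.4 against 109 ± 35.7 CPM (2.50 ± 0.16). Genes lower by rule included CACNG4, a calcium channel subunit, at 28.0 ± 4.90 against 307 ± 44.1 CPM (-3.45 ± 0.21), NXPE3 (-3.51 ± 0.24) and LRP1 (-4.30 ± 0.33). Genes higher by rule included the Wnt antagonist NKD1 and the guanylate-binding protein GBP5, at least 20.2-fold and 16.6-fold.

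In the deposited rows 2579 of 12012 were higher and 2455 lower after FEBJ than after cynaroside by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2019 and 1834 of them more than 2-fold, and with the scaling of the opposite-strand reading 3279 were higher and 1987 lower. The median log2 fold change moved from 0.12 to 0.37 with that scaling. COL1A1 (-3.31 ± 0.36), FN1 (-0.82 ± 0.19) and the TGFB1 row opposite HNRNPUL1 (-1.16 ± 0.07) were lower after FEBJ. PDGFRB (adjusted p = 0.280), TIMP1 (0.481), the ACTA2 row (0.568) and CCN2 (0.752) were not called. COL3A1 was at least 3.34-fold lower (adjusted p = 0.0355), a bound that rested on cynaroside 2, without which the log2 fold change was 0 and the adjusted p was 1. The call also ended without DMSO 1 (0.0537), DMSO 2 (0.0971), FEBJ 1 (0.0913) or FEBJ 2 (0.130), and with a replicate block (0.0560). All 13 mitochondrial mRNA rows were lower (adjusted p = 2.88e-22, or an adjusted p = 0.725 with an estimated correlation), the only list of 29 past the threshold in camera. Here too the strand of their reads is uncertain, so levels of the named genes cannot be read from them. SERPINA1 was at least 19.2-fold higher and KRT8 was higher (1.30 ± 0.07).

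The changes after the 2 treatments were then compared gene by gene. Of 1443 genes in the opposite-strand reading, 148 rose and 161 fell after both treatments, where independent lists of these sizes would share 103 and 107. In addition, 79 rose after FEBJ and fell after cynaroside, and 79 fell after FEBJ and rose after cynaroside, where independent lists would share 111 and 99.4. TPM1, HMGCS1 and SLC1A5 fell after both, BCL2L11 and NR4A1 rose after both, and KRT7, IER2 and IER3 rose after FEBJ and fell after cynaroside. The log2 fold changes correlated at r = 0.309 with a covariance of 0.401. Over 20 simulated draws of unchanged treated groups, the mean r was 0.0464 and the mean covariance 0.00499. The highest simulated r was 0.327, above the observed value, and the highest simulated covariance was 0.0364, below it. The draws kept the observed DMSO counts and centred the treated groups on their means, so noise of the shared libraries largely cancelled. They therefore cannot show how much correlation shared libraries give, and independent lists do not allow for shared libraries either. In the deposited rows r was 0.545 with a covariance of 2.30, against 0.101 and 0.0333 in the draws, and 1490 rows rose and 1449 fell after both. With FEBJ set against 1 DMSO library and cynaroside against the other, so that none was shared, r was 0.242 and 0.257 in the opposite-strand reading and 0.466 and 0.475 in the deposited rows. Without cynaroside 2 the opposite-strand r was 0.185 while without DMSO 2 it was 0.481.

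**Figure D4:**
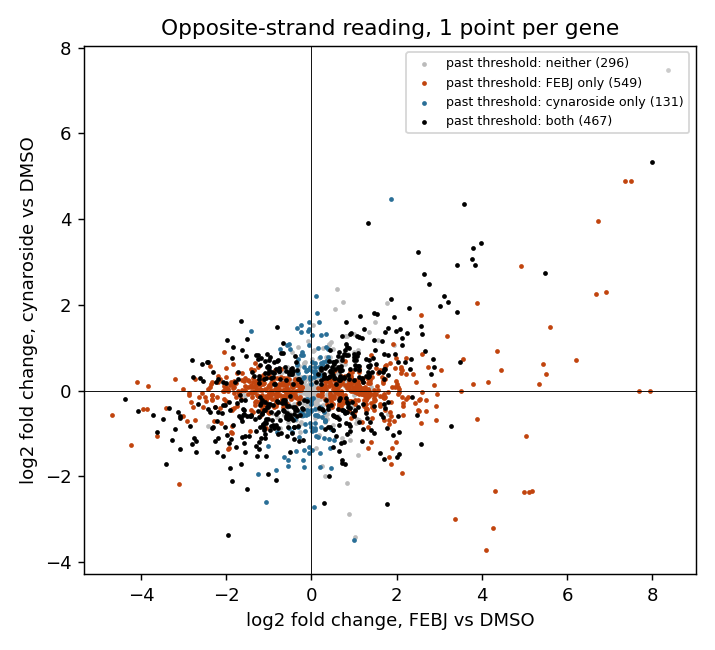
Log2 fold change after FEBJ (x axis) and after cynaroside (y axis), each against DMSO, for 1443 genes of the opposite-strand reading, with 1 point per gene coloured by the comparisons in which it passed the threshold. Changes after FEBJ spread wider, with 549 genes past the threshold after FEBJ only, 131 after cynaroside only and 467 after both.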

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

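No tests were run on the shares below, and their comparison with DMSO was a rule for parts of the tables that the report did not analyse. Reads that overlapped more than 1 feature made up 0.168% of all counts after FEBJ (0.167 to 0.170%), 0.152% after cynaroside and 0.159% in DMSO. Reads that overlapped no feature made up 87.5% after FEBJ and 87.9% in DMSO. Unaligned reads made up 1.88% after cynaroside (1.80 to 1.96%) and 2.54% in DMSO. Reads that aligned to more than 1 place made up 2.98% after FEBJ (2.93 to 3.02%), 3.63% after cynaroside (3.61 to 3.64%) and 2.79% in DMSO. For each share given, both libraries of the treatment lay outside the range of the DMSO libraries. The cause was not tested.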

How the results depend on the processing

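The tests of the opposite-strand reading, its scaling, the fit without protein-coding rows that have no opposite exon, the one with coding features and the one with split DMSO libraries were chosen after the result was seen. The other alternatives were chosen before.

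Most results kept their side. Of the counts, lists and correlations under each alternative 213 kept their value and 39 moved, which for counts and lists means by a factor of more than 1.5 and for correlations by more than the SD of the values with 1 library left out. For deposited rows picked by the naming rule, 1282 values kept their side of the threshold, 52 lost a call, 7 gained a call and 1 changed sign. These rows include the largest rises and falls of the deposited rows, most of which are not printed here. Of 87 such results, 74 kept their side under every alternative, and the other 13 were all panel or marker rows. In the opposite-strand reading 1314 values kept their side and 77 lost a call. Of 127 results, each a gene in a comparison, 95 kept their side under each of 11 alternatives that gave them a value. Upper-quartile scaling, no filter, the filter of 1 CPM, the fit of only the 4 libraries compared and the prior count of 2 were not among these 11. A few results had no value under some alternatives.

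In the deposited rows the rises after FEBJ, 3125, became 2026 without protein-coding rows with no opposite exon. The rises after cynaroside, 2917, became 1428 with the scaling of the opposite-strand reading, 1550 without those rows and 1506 with a threshold fold of 1.5. The falls after cynaroside, 2537, became 1628 without those rows and ranged from 1543 to 2649 when 1 library was left out. The STAB1 row changed sign after cynaroside, from 0.42 to -0.0459, with the scaling of the opposite-strand reading.

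The list tests depended most on the method. With an estimated correlation camera placed 0 lists past the threshold in the deposited rows for FEBJ against DMSO, 0 for cynaroside against DMSO and 0 for FEBJ against cynaroside, in place of 11, 15 and 1. The fry test, which asks whether a list moves on balance one way, placed 24 past it for FEBJ against DMSO and 14 for FEBJ against cynaroside. For FEBJ against cynaroside leaving out 1 library gave 1 to 5 lists. In the opposite-strand reading an estimated correlation gave 0 lists for FEBJ against DMSO and 0 for FEBJ against cynaroside, in place of 3 and 3. The fry test gave 2 for cynaroside against DMSO and 5 for FEBJ against cynaroside. With RLE scaling 2 lists passed for FEBJ against DMSO, in place of 3.

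In the opposite-strand reading with coding features too, 806 genes rose and 785 fell after FEBJ, 500 and 520 after cynaroside, and 796 and 786 for FEBJ against cynaroside. With a threshold fold of 1.5, 333 genes rose after FEBJ, 49 rose and 76 fell after cynaroside, and 320 were lower after FEBJ than after cynaroside.

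The correlation of the 2 treatments in the deposited rows, 0.545, ranged from 0.437 to 0.619 when 1 library was left out and was 0.477 without protein-coding rows with no opposite exon. With the DMSO libraries split between the treatments it was 0.466 and 0.475. In the opposite-strand reading, 0.309, it ranged from 0.185 to 0.481.

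With the replicate number as a replicate block 2986 rows rose and 2776 fell after FEBJ, 2800 and 2310 after cynaroside, and 3 lists passed for FEBJ against cynaroside. It ended the calls of the ACTA2 row (0.114) and TIMP1 (0.0844) after FEBJ, and of COL3A1 (0.0560) and, in the opposite-strand reading, LOXL4 (0.0534) for FEBJ against cynaroside. Libraries with the same number did not deviate together, with correlations of -0.013, 0.0015 and -0.0068 across 12012 rows.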

Other observations

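The tests of the 1st pattern weighed here were chosen after the result was seen, as were those of genomic DNA, transcript levels and chromosome copy number in the others, and the genes of this and the next paragraph were chosen after their values were seen. Several list members outside the naming rule moved strongly in the opposite-strand reading. COL4A2, a chain of basement membrane collagen, fell after FEBJ from 1380 ± 5.11 to 334 ± 16.3 CPM (-2.04 ± 0.08) and was at 1385 ± 83.0 CPM after cynaroside (adjusted p = 0.980 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). COL5A3, a chain of type V collagen and the other collagen tested, rose after FEBJ (2.56 ± 0.84, adjusted p = 0.00380), a call that ended at 0.144 without DMSO 1, 0.298 without FEBJ 2 and 0.0551 with DESeq2. NGFR, a neurotrophin receptor listed among quiescent stellate cell markers, rose after FEBJ from 84.7 ± 7.80 to 649 ± 30.1 CPM (2.93 ± 0.16) and was higher than after cynaroside (3.27 ± 0.17). XPC, a p53 target that recognises DNA damage, rose to 2792 ± 134 CPM after FEBJ (1.69 ± 0.06), while MDM2, another p53 target, fell (-0.66 ± 0.12). STEAP3, a metalloreductase of the ferroptosis list, fell after FEBJ (-2.64 ± 0.20). The other calls of this paragraph after FEBJ kept their side under every alternative except the fall of MDM2 with a threshold fold of 1.5.

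NOB1, an endonuclease that matures ribosomal RNA, rose after FEBJ (1.30 ± 0.09) and fell after cynaroside (-0.64 ± 0.10), and the direct comparison was 1.94 ± 0.09. CHAF1A, which loads histones onto new DNA, rose after FEBJ (1.80 ± 0.13) and less after cynaroside (0.36, adjusted p = 0.0248), a call that ended at 0.281 without DMSO 2, 0.0672 without cynaroside 1 and 0.0704 without cynaroside 2. PLK1, a mitotic kinase of the G2/M list, fell after cynaroside (-0.76 ± 0.08) and was not called after FEBJ (adjusted p = 0.384 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HMMR, a spindle protein of the same list, rose after FEBJ (1.01 ± 0.08) and after cynaroside (0.25, adjusted p = 0.00892), the latter ending at 0.267 without DMSO 2 and 0.162 without cynaroside 1. HSPA4L, a heat shock protein of the HSP110 family, rose after FEBJ (2.66 ± 0.30) and after cynaroside (0.92, adjusted p = 0.0145), the latter ending at 0.108 without DMSO 1 and 0.0601 without cynaroside 1. NDUFS7, a subunit of respiratory complex I, rose after FEBJ (1.07 ± 0.06).

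Non-coding rows held more counts than the protein-coding rows opposite to them. Counting without regard to strand was excluded, as it needs over 50%, and across all 1157 pairs the own row held a median of 9.59% of the opposite row in DMSO 1, the highest library, with intervals up to 10.8% in DMSO, 8.70% after FEBJ and 4.98% after cynaroside. The exclusion rests on the bound of 50% and was set after the values were seen, since the DMSO intervals did not stay under the lower bound of 10% first written for it. MT-ND6 held at least 50.3% of mitochondrial mRNA counts, just past the bound of 50% written against antisense transcription in the cells. That explanation stays open for the nuclear rows, because MT-ND6 is a single mitochondrial row and not one of them. Strand-marked reads that were counted on the opposite strand may also explain the pattern, but 77.8% of 1157 rows held more counts than the gene opposite, under the bound of 80% set for this explanation, so it stays open.

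Protein-coding rows with no opposite exon were lower after both treatments. A larger share of reads on the other strand in the DMSO libraries could explain this and stays open. The excess in DMSO rose with the opposite count across 801 genes (rank correlation 0.413). However, the excess was an absolute difference in CPM, which also grows with abundance when own rows fall in proportion. The correlation therefore cannot tell this explanation from lower transcript levels. More genomic DNA in DMSO stays open, as 55 marker rows of other cell types held 15.7% of the counts per kb of other protein-coding rows. Across the 801 genes, the rank correlation of the DMSO excess with exon length was 0.112, for which no bound had been set. Lower transcript levels stay open for both treatments. The opposite-strand medians of 625 genes, -0.19 after FEBJ and -0.0172 after cynaroside, come from a scaling that centres them near 0. They also come from genes that have opposite rows. The ratio of own to opposite row needs no scaling, and in 1157 pairs its median was 9.59 and 9.41% in DMSO. It was 7.09 and 7.35% after FEBJ, with intervals that overlapped those of DMSO. After cynaroside it was 4.09 and 3.92%, with intervals that did not. A fall of transcripts alone would leave this ratio unchanged if both rows held reads of the same transcript. That was not shown, and the pairs lie outside this class. The falls of COL1A1 and FN1 in their own rows could be larger than those of their transcripts if the other-strand share is the cause.

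More genes passed the threshold after FEBJ than after cynaroside in the opposite-strand reading, 1016 against 598. Unequal depth was excluded, as the ratio was 1.84 after all libraries were thinned to the smallest total. Without the 10 most abundant genes, which held 37.0% of the counts of this reading, the ratio was 1.71. TMM scaling already trims extreme genes, so this test had little room to show a few abundant genes as the cause. Other chromosome copy numbers in the FEBJ libraries stay open, since medians of 84 runs of neighbouring genes had an SD of 0.320, inside the shuffled range with its mean of 0.305. A higher dose or a broader action of FEBJ might also give the pattern, and the labels give no doses to weigh it.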
